A study of Drosophila melanogaster with 3 samples.

How the data were processed

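ChIP-seq peak lists of 3 biological replicates of Bab1-GFP adult females were analysed, with sample groups and replicate numbers taken from the labels. Per the labels, chromatin of whole flies was sheared by sonication, the antibody was against GFP and the genome build was dm6. The replicates are labelled biological, and nothing in the labels says whether flies of separate cultures were used, so spreads between replicates measure these 3 samples only.

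The deposited files were peak lists in the narrowPeak layout, with 30000 peaks per replicate and in the pooled list. Per the deposited file listings, each list was called against 1 control library, which was not used here. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The signal values, deposited by the authors for each peak, come from the peak caller and are comparable only within a list. The −log10 q values deposited by the authors were not used for ranking, because many peaks share the highest value and all IDR peaks hold the same one. The deposited summit offsets gave the summit of each peak; it lay at or past the peak's end in 1 row of the IDR list and in 3 to 6 rows of the other lists, and these rows were kept. Each of the 6896 IDR peaks occurs unchanged in the pooled list, where they are the 6896 peaks with the highest signal values. The exact number of 30000 peaks in each replicate list means that a list's length says nothing of its depth, and no error-rate threshold was applied here to the weak end of each list. Strength was compared by rank, and each replicate was represented by its 6896 strongest peaks, so that all lists had the same length.

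Genes, transcripts and TSSs came from the Ensembl release 115 annotation of BDGP6.54, and sequence from the RefSeq release of the same assembly; no peak ran past a chromosome's end, and no peak lay on Y or off the main chromosomes. Transposon genes were left out, which left 18164 genes. Coordinates are 1-based on dm6. A summit was assigned to the first class that held it, in the order promoter (1000 bp upstream to 100 bp downstream of a TSS), 5′ untranslated region, coding exon, 3′ untranslated region, other exon, intron and intergenic. A gene carried a peak if a summit lay in the gene body or the 1 kb upstream.

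The comparisons and their tests were fixed before the data were examined. Overlap between replicate lists and location were compared with 1000 circular shifts of all summits within chromosomes. The same shifts, fixed for the IDR peaks found in every replicate, are not reported as a test, because the IDR list is built from the same replicates. The density on X was compared with the large autosome arms by 100000 permutations of 1 Mb windows. Each of 29 gene lists was compared with 10000 random lists drawn from 20 bins of gene length, two-sided, which permutes list membership among genes of similar length, with Benjamini-Hochberg adjustment and a threshold of 0.05. For bab1 and bab2, peak counts were compared with 10000 random draws, with replacement, from the genes of the same length bin. The 2 symbols bric and Tkr of the BTB list had no match in the annotation. Intervals of shares are exact (Clopper-Pearson) at 95% and cover counting error only, since peaks and genes are not independent.

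For 16 sequence patterns and all sequences of 6 bases, a window of 101 bp at each summit was compared with windows of the same size centred 500 bp to either side. The sign test fixed for this failed on simulated data: it called 100% of 200 simulated comparisons with no difference, at flank shares of 0.02 and 0.1. It was replaced, after the data had been seen, by an exact permutation of the 3 windows within each peak, which called 5% and 4.5% of the same simulated comparisons and recovered 77% of those with a 1.3-fold difference at a flank share of 0.02. On the deposited data the test first fixed would have called 14 of 16 patterns and the replacement called 10. The gene list test, checked on simulated lists drawn at random from 18164 genes, called 0% with no effect, 81% with odds multiplied by 4 and 99.5% with odds multiplied by 8. The simulated genes carried peaks independently of each other, so these rates do not cover lists of neighbouring genes that share a peak.

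The text names the 20 strongest IDR peaks among those found in all 3 replicate top lists, every IDR peak at bab1 and bab2, the 4 members with the strongest peak of each gene list past the threshold or among the 3 highest or lowest ratios, the genes y, e, t and Ddc in any case, and the 5 sequences of 6 bases with the largest ratio past the threshold.

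The alternatives tried were another overlap rule (reciprocal overlap of at least 50%, or summits within 100 bp), whole replicate lists, fewer peaks, each replicate left out (IDR peaks with a summit in the top lists of both others), promoters of 250 bp on either side of a TSS, other density windows, other rules of gene assignment and chance, and other motif windows and backgrounds. A peak set without a replicate still draws on the IDR list of all 3 replicates, and drops each peak that either of the others lacks. Such sets share the peaks found in all 3 top lists, so they are not independent of each other. Gene lists matched on length and gene type, the IDR peaks found in all 3 top lists, 7 further gene lists, and the count of pooled-list peaks at bab1 and bab2 were added after the data had been seen. Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.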

Results

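The series measured where Bab1 lies on the genome of adult female fruit flies. Bab1 (Bric-a-brac 1) is a transcription factor with a BTB domain and a DNA-binding domain of the pipsqueak type, known for its roles in abdominal pigmentation, in the terminal filaments of the ovary and in the segments of the legs and antennae. Per the labels, a transgenic Drosophila melanogaster line carried Bab1 fused to GFP at its C terminus, chromatin of whole females was sheared by sonication, and an antibody against GFP was used for chromatin immunoprecipitation followed by sequencing (ChIP-seq). There was 1 group of 3 biological replicates and no second group, so the comparisons are between replicates, between peaks and chance positions, and between gene groups. The deposited peak lists held 30000 peaks for each replicate, 30000 for the pooled replicates and 6896 in the list that passed the authors' test of reproducibility between replicates (the irreproducible discovery rate, IDR). No library of untagged flies was used here. The agreement of replicates, the location of peaks, the gene lists and the sequence patterns below therefore do not separate binding by Bab1 from background of the immunoprecipitation. Read counts were not used here, so the depth of each library is unknown from these lists. The top list of a replicate below means its 6896 peaks with the highest signal values.

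The first comparison asked how far the replicates found the same sites. Of the 6896 summits in a replicate's top list, 68.7% ± 1.71 (mean ± SD over 6 ordered pairs of 3 replicates) lay inside a peak of another replicate's top list, from 66.7% (replicate 3 in replicate 1) to 71.2% (replicate 1 in replicate 2). Shifting the summits around each chromosome gave 1.63%, and the highest share in 1000 shifts of any pair was 2.78% (one-sided permutation p = 0.001, the smallest the shifts can give). Shifted summits mostly leave the promoters, where most summits lay, so lists centred on promoters for any reason would exceed this level. Across the IDR peaks shared by a pair of replicates, Spearman's rho of the signal values was 0.722 for replicates 1 and 2 (4790 peaks), 0.692 for replicates 1 and 3 (4441 peaks) and 0.654 for replicates 2 and 3 (4610 peaks). These correlations run across peaks, which are not independent replicates. The IDR peaks were also selected for reproducibility between these same replicates, so the correlations describe the list. No row was identical between any pair of replicate lists.

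Of the 6896 IDR peaks, 3932 (57.0%, exact 95% confidence interval 55.8% to 58.2%) had their summit in the top lists of all 3 replicates. The IDR list rests on the pooled data of the same replicates and was selected for reproducibility between them, so this share describes the list and is not a test against chance. A further 2045 (29.7%) were found in exactly 2 top lists, 862 (12.5%) in exactly 1 and 57 (0.827%) in none. Replicate 2 held 5911 of the IDR summits, replicate 1 held 5523 and replicate 3 held 5314. The intervals cover counting error only. The share in all 3 replicates was 36.0% when peaks had to overlap by at least 50% of both lengths and 90.8% when whole replicate lists were used.

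At the tagged gene itself, bab1 (FBgn0004870, dm6 chromosome 3L, 1036369 to 1101089, minus strand), the IDR list held 5 peaks, all in introns. The strongest lay at 1084323 to 1084746, with a signal value of 369.3 and rank 2632 of 6896, and was in the top lists of all 3 replicates. The others lay at 1083401 to 1083591 (rank 5342), 1093060 to 1093193 (rank 5689), 1098505 to 1098928 (rank 6800) and 1085764 to 1086187 (rank 6887). They were found in the top lists of 1, 2, 0 and 1 replicates, in that order. The replicate top lists themselves held 3 ± 1 peaks at bab1 (mean ± SD, n = 3). The neighbouring paralog bab2 (FBgn0025525, chromosome 3L, 1140429 to 1177276, minus strand) had no IDR peak.

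Genes matched to bab1 on length held 1.77 IDR peaks on average, and 88.1% of them held fewer than 5, so the count at bab1 was not beyond chance (two-sided permutation p = 0.239 against 10000 random draws of genes). At bab2 the same test (permutation p = 0.848) could not have shown a lack of peaks, since 42.4% of its matched genes also had none. No conclusion is drawn from it. With peaks required in the top lists of any 2 replicates, the count at bab1 was 1 or 2, and it was 1 among the strongest 3448 IDR peaks.

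**Figure D1:**
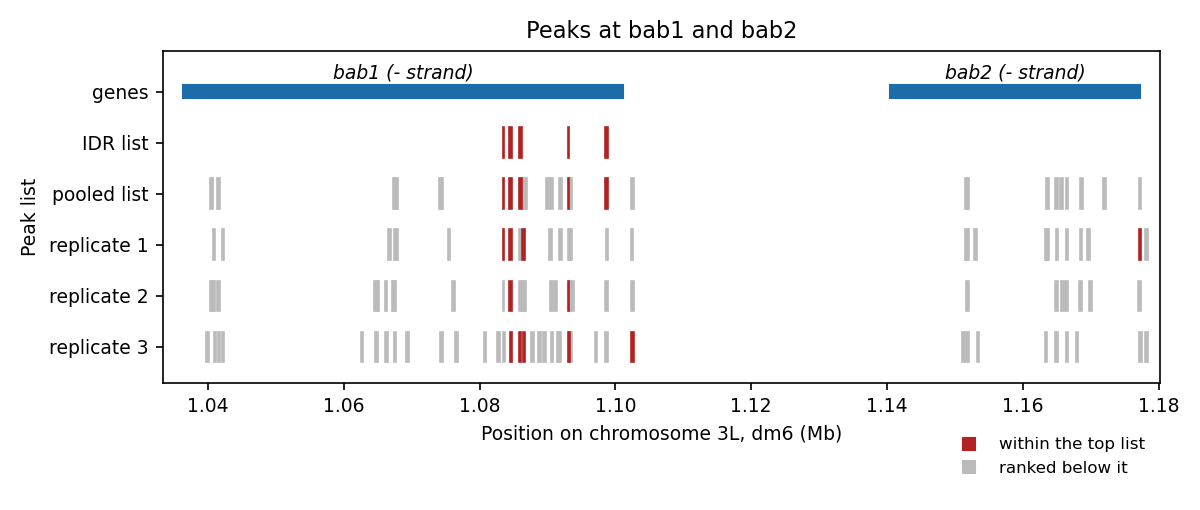
Peaks at bab1 and bab2 on chromosome 3L (position in Mb, dm6) in the IDR list, the pooled list and the 3 replicate lists. Red boxes are peaks within the top 6896 of their list and grey boxes are ranked below it; the 5 red boxes of the IDR list all lie within bab1.

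The strongest sites were mostly promoters. The peak with the highest signal value, 9887, lay in an intron of CG11050 (chromosome 2L, 6612249 to 6613129). It was followed by promoter peaks at Sptr, which encodes sepiapterin reductase of tetrahydrobiopterin synthesis (X, 8464218 to 8464826, signal 8877), between Ugalt, a nucleotide sugar transporter gene, and eIF2Bbeta, a translation initiation factor gene (X, 2703621 to 2704105, signal 6908), at Gapdh2 of glycolysis (X, 15867740 to 15868324, signal 5824), and at CG14100 (3L, 19590404 to 19590841, signal 5380.25). Of the 20 strongest peaks, 14 lay in promoters, 5 in introns and 1 between genes, and all 20 were in the top lists of all 3 replicates.

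Among the rest of these 20, promoter peaks lay at genes of the mitochondrial ribosome, namely mRpL41 with its neighbour CG8079 (signal 5312), mRpS10 with Art3 (4493) and mRpS23 with CenG1A (3549). Others lay at Trf2, a relative of the TATA-binding protein, with lawc (signal 3937), at Mtl, a Rac-type GTPase gene, with CG5611 (3907), at Elp5 of the Elongator complex with CG1275 (3672), and at Chro, a chromatin protein gene, with Ssl1 of the transcription factor TFIIH (3476). Promoter peaks at CG11309 with CG7632 (4817), at CG1888 (3824) and at CG13390 with CG17294 (3749) complete the promoters. The intronic peaks were in CG32772 (5196), in norpA, which encodes the phospholipase C of phototransduction (4311), in CG12769 (3790.21) and in Tlk, a protein kinase gene (3780.24). The peak between genes (signal 3613) had its nearest transcription start site (TSS) at CG31668, 3748 bp away. Signal values are the authors' and rank peaks within a list only, so they carry no error between replicates.

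Peak summits concentrated at promoters. Of the IDR summits, 72.7% lay from 1000 bp upstream to 100 bp downstream of a TSS, against 14.6% of shifted positions, a ratio of 5.00, and the replicate top lists gave 70.9% ± 0.570 (SD, n = 3). The median distance to the nearest TSS was 114 bp, against 2842 bp after a shift, and 66.0% of summits lay within 250 bp of a TSS. Introns held 19.1% of summits against 39.1% of shifted positions, intergenic DNA 4.22% against 25.5%, coding exons 0.595% against 14.1%, 3′ untranslated regions 0.899% against 4.10% and other exons 0.624% against 1.13%. For these classes and for promoters the difference had an adjusted permutation p of 0.00233 (two-sided, 1000 circular shifts, Benjamini-Hochberg over 7 classes), which rests on the smallest p the shifts can give. 5′ untranslated regions outside promoters held 1.87% against 1.53% (adjusted permutation p = 0.048).

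**Figure D2:**
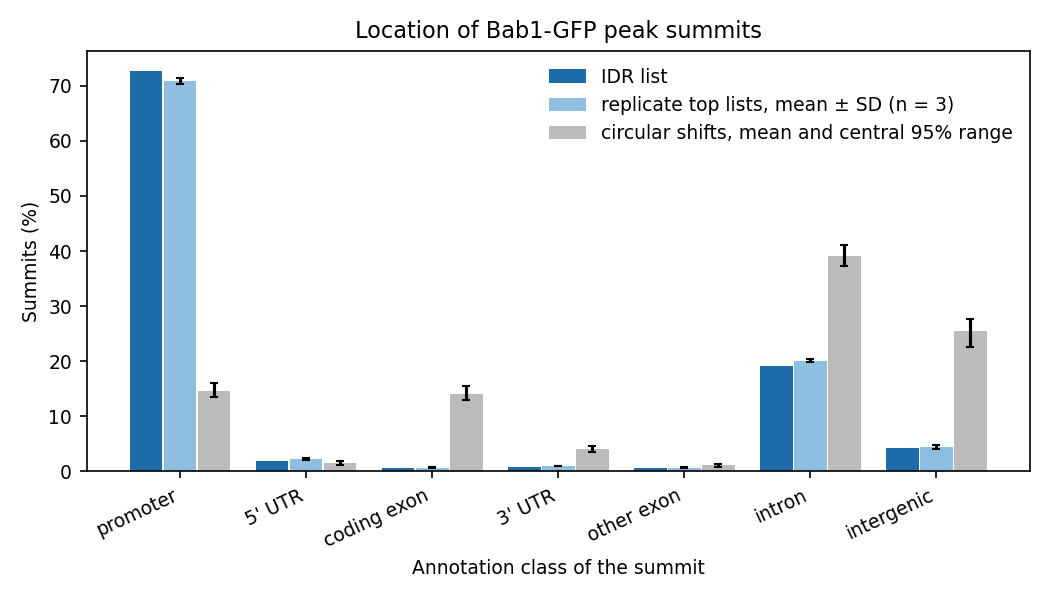
Share of summits in each annotation class (percent of summits) for the IDR list, the replicate top lists (mean ± SD, n = 3) and circularly shifted positions (mean and central 95% range). Promoters held 72.7% of the IDR summits and 14.6% of shifted positions.

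The weakest quartile of IDR peaks lay less often in promoters than the others, and the share did not rise steadily with strength. The promoter share was 66.6% (exact 95% confidence interval 64.4% to 68.9%) in the weakest quartile of IDR peaks, 73.8% in the next, 76.9% in the next and 73.5% (71.3% to 75.6%) in the strongest, with 1724 peaks in each. Across peaks, Spearman's rho between signal value and promoter location was 0.0662 in the IDR list, and 0.0883, 0.0813 and 0.131 in the top lists of replicates 1, 2 and 3 (permutation p = 1e-05 in each, the smallest that 100000 permutations give; adjusted over the 4 lists also 1e-05). With promoters drawn as 250 bp on either side of a TSS, rho in the IDR list was 0.032 (permutation p = 0.00795). Peaks are not independent replicates.

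The X chromosome carried more peaks per Mb than any other chromosome. It held 62.8 IDR summits per Mb, while 2L held 48.1, 2R 53.6, 3L 47.5 and 3R 48.2, chromosome 4 held 34.9, and the Y held none. The replicate top lists gave 63.3 ± 0.701 on X and 35.4 ± 2.14 on chromosome 4 (SD, n = 3). Over windows of 1 Mb, X held 64.2 ± 26.9 summits (SD over 23 windows) and the large autosome arms 49.6 ± 26.1 (108 windows), a ratio of 1.29 (two-sided permutation p = 0.0174, 100000 permutations of windows). The ratio was 1.31 ± 0.0195 over the replicate top lists (SD, n = 3). Windows on a chromosome are neighbours and not independent.

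Gene groups differed widely in how many members carried a peak. Of 18164 annotated genes, 6864 (37.8%) had at least 1 IDR summit in the gene body or the 1 kb upstream, and each of 29 gene lists was compared with 10000 random lists matched on length. Ribosomal protein genes were covered almost completely, with 82 of 86 carrying a peak against 29.5 for matched genes (ratio 2.78, adjusted permutation p = 0.000828), and 94.2% ± 2.01 of them carried a peak in the replicate top lists (SD, n = 3). Genes of proteasome subunits, which form the protease that degrades ubiquitin-tagged proteins, followed with 25 of 32 (ratio 2.09, adjusted permutation p = 0.000828, replicates 86.5% ± 3.61). Cell cycle genes had 24 of 28 (ratio 1.72, adjusted permutation p = 0.00145, replicates 78.6% ± 7.14). Genes of tRNAs had 91 of 295 (ratio 1.69, adjusted permutation p = 0.000828, replicates 30.1% ± 4.27).

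The strongest peaks at ribosomal protein genes lay at RpL24 (chromosome 2L, 13394884 to 13395442, signal 2021), RpL32 (3R, 30045915 to 30046738, signal 1374), RpS25 (signal 1312) and RpL34b (signal 1299), all in promoters. Among proteasome genes they lay at Rpn2 (signal 689.5), Rpn3 (586.4), Rpn6 (584.7) and Rpn5 (555.9). Among cell cycle genes they lay at E2f1, a transcription factor of S phase entry (3R, 21632499 to 21633314, signal 2147), aurA, a mitotic kinase (789.9), CycE, the cyclin of S phase entry (620.6), and dup, a replication licensing factor (562). The nearest TSS belonged to another gene for RpS25 (CG4820), Rpn2 (Slbp), Rpn5 (Hat1), aurA (CG3281) and dup (SRPK). The strongest peaks at tRNA genes were shared by tRNA:Tyr-GTA-1-7 and tRNA:Tyr-GTA-1-8 (signal 1415), or lay at tRNA:Val-TAC-1-1 (1252), with CG46456 and lama nearest, and tRNA:His-GTG-1-2 (590.6), with CG8490 nearest.

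The cell cycle call was lost without replicate 1 (ratio 1.35, adjusted permutation p = 0.336), without replicate 3 (1.53, adjusted permutation p = 0.0797) and among the strongest 3448 peaks (1.66, adjusted permutation p = 0.0723). The tRNA call was lost among the strongest 3448 peaks (1.37, adjusted permutation p = 0.0706) and turned to fewer peaks against lists without length matching (0.817, adjusted permutation p = 0.0272), and over all settings the ratio ran from 1.73 to 9.06 for ribosomal protein genes and from 1.71 to 6.94 for proteasome genes.

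Of the 29 lists, 6 carried fewer peaks than matched genes. Chemosensory receptor genes, which act in taste and smell neurons, had a peak at 8 of 185 (expected 75.7, ratio 0.106, adjusted permutation p = 0.000828, replicates 4.32% ± 0.541, SD, n = 3). Genes of neuronal function, mostly ion channels, transmitter receptors and synaptic proteins, had 3 of 33 (ratio 0.157, adjusted permutation p = 0.000828, replicates 12.1% ± 3.03), neuroblast and neural fate factors 4 of 27 (0.294, adjusted permutation p = 0.000828) and muscle structure genes 5 of 26 (0.352, adjusted permutation p = 0.000828). Photoreceptor genes had 6 of 25 (0.453, adjusted permutation p = 0.0226) and genes that pattern appendages along the proximodistal axis, a list that includes bab1 and bab2, had 9 of 28 (0.564, adjusted permutation p = 0.0418; 0.317, or 4 genes, without replicate 2).

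Some members of these lists nevertheless carried a peak, in promoters unless stated. The 3 neuronal genes were elav, an RNA-binding protein gene of neurons (X, 523262 to 523701, signal 2441), dnc, a phosphodiesterase gene (775.4), and Syx1A, a syntaxin gene (663). Among neural fate factors they were Syp (signal 3476), brat (612), Imp (252) and nub (210.5, in the top list of 1 replicate). The strongest peaks at the 9 appendage genes were those at Dll, a homeodomain gene of distal limb identity (2R, 24814556 to 24814931, signal 1708), ct (intron, 343.1) and Lim1 (296.6), beside bab1 (introns). Photoreceptor genes with a peak included norpA (intron), Rh5, an opsin gene (856.3), rdgB (467.7) and rdgA (386.2), and muscle genes included Mef2, a muscle transcription factor (intron, 593.4), TpnC73F (382.1), Zasp52 (324.2) and Tm1 (274.1). The peaks at rdgA and TpnC73F lay nearest the TSS of CG10962 and Pop5, and those at the chemosensory genes Ir7c (701.5), Or9a (689.9), Gr32a (388.6) and Gr5a (301.1) lay nearest dec, Neb-cGP, Idua and Tre1. Peaks at Tm1 and Gr32a were absent without replicate 1 and without replicate 2, that at Zasp52 without replicate 1, those at Gr5a without replicate 1 and without replicate 3, and that at nub without any one of the replicates (0 peaks in each case). These sets keep only peaks in the top lists of both other replicates. The strongest peaks at Tm1 and Gr32a dropped out because the top list of replicate 3 lacked them. Those at Zasp52 and Gr5a were lacking in replicate 2, and that at nub was in the top list of replicate 3 only.

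The photoreceptor call was lost without any one of the replicates (ratios 0.467 to 0.491, adjusted permutation p 0.0797 to 0.109) and among the strongest 3448 peaks (0.595, adjusted permutation p = 0.294). Without length matching the appendage (0.848), muscle (0.507) and photoreceptor (0.635) calls were lost, and against circular shifts those and the neuroblast call (0.503) were lost, while the ratio ran from 0.0548 to 0.387 for chemosensory and from 0.156 to 0.344 for neuronal genes over all settings.

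Genes of cuticle pigmentation, a process in which Bab1 has a known role, had a peak at 6 of 22 (expected 11.4, ratio 0.525, adjusted permutation p = 0.0647, replicates 27.3% ± 4.55, SD, n = 3), which did not pass the threshold. Of the named enzymes of this pathway, yellow (y), ebony (e) and Ddc had no IDR summit in the gene body or the 1 kb upstream. Peaks farther from these genes were not counted for them. The tan gene (t) had 1, in an intron (X, 9220594 to 9220716, signal 253.1, rank 5098), which was in the top lists of all 3 replicates. Among the strongest 3448 peaks, where the peak at t is not included, the pigmentation list had 1 gene with a peak (ratio 0.143, adjusted permutation p = 0.0199). The ratio of this list ran from 0.143 to 1.28 over all settings, so its direction was not kept. Hox genes had 1 of 8 (ratio 0.214, adjusted permutation p = 0.0564), at Antp (intron, signal 266), with the start of a non-coding RNA nearest.

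No other list passed the threshold. Genes of Polycomb, trithorax and insulator proteins had 25 of 34 (ratio 1.37, adjusted permutation p = 0.0647), and passed it in each set that left out a replicate (1.55, 1.57 and 1.56, adjusted permutation p 0.0393, 0.0261 and 0.0246 without replicates 1, 2 and 3). Each of these sets holds the 3932 peaks found in all 3 top lists, so they are not 3 independent results. Ratios above 1 that did not pass were those of ecdysone response and synthesis (1.36), insulin, TOR and FOXO signalling (1.35), germline and oogenesis (1.32), heat shock and stress (1.32), innate immunity (1.31), lipid and carbohydrate metabolism (1.28), eggshell and yolk (1.26), and the Hippo (1.25), Notch (1.23), EGFR and JAK/STAT (1.21), Hedgehog and Dpp (1.14) and Wnt (1.14) pathways, with adjusted permutation p from 0.149 to 0.587. BTB domain transcription factors (1.13), the circadian clock (1.12), abdominal patterning and sex determination (0.732), and the ovarian niche and follicle cells (0.700) did not pass either, with adjusted permutation p of 0.677, 0.814, 0.328 and 0.167. Several lists hold neighbouring or clustered genes that can share a peak, so genes within a list are not independent.

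**Figure D3:**
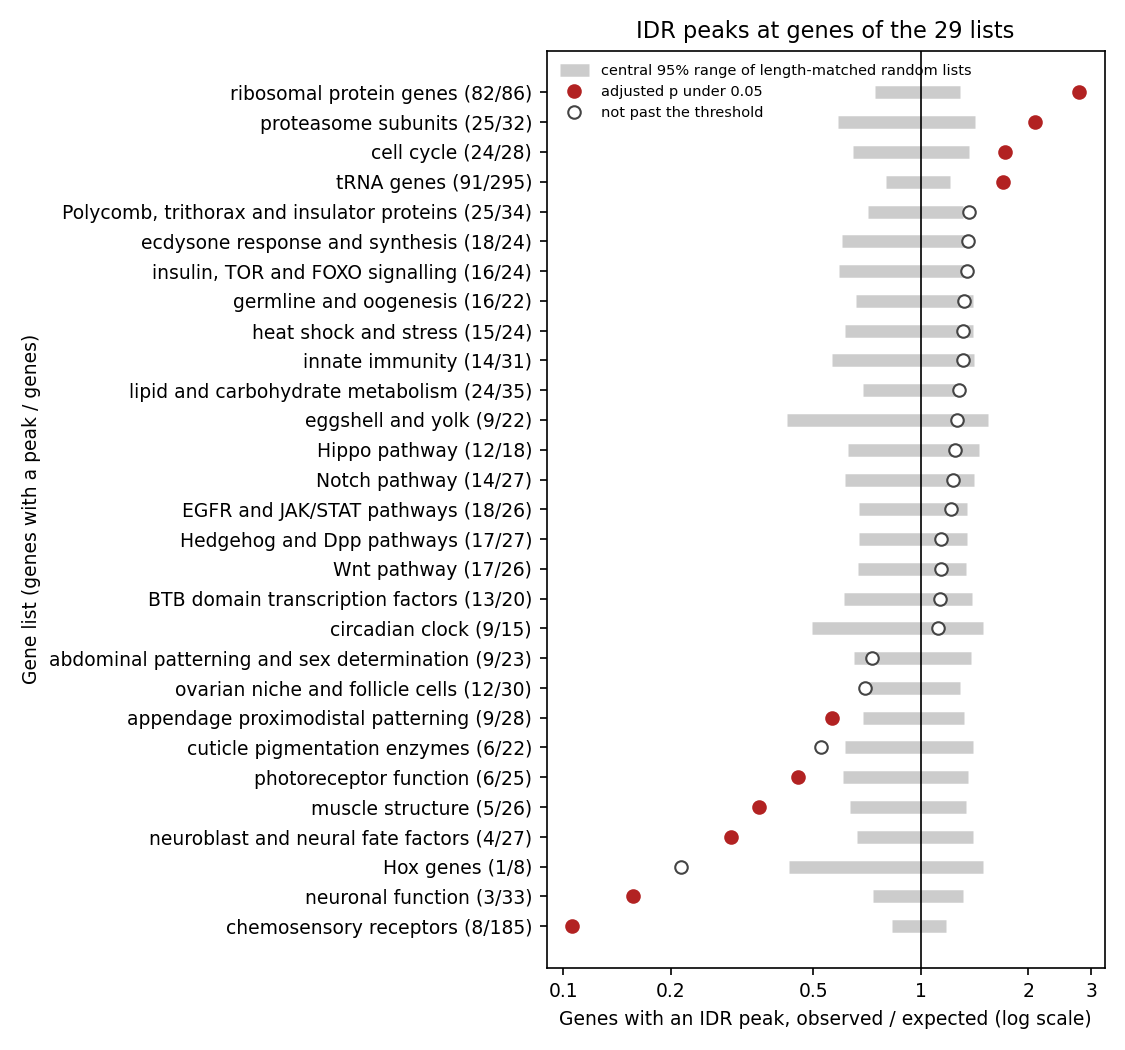
Genes with an IDR peak in each of the 29 gene lists, as observed over expected (log scale), with the central 95% range of length-matched random lists in grey. Ribosomal protein genes stand highest (2.78) and chemosensory receptors lowest (0.106); filled points have an adjusted p under 0.05.

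In the full IDR list, promoter elements had the largest ratios of the 16 patterns at the summits, an order that changed in other peak sets. The DNA replication-related element (DRE, TATCGATA), a core promoter element bound by the factor Dref, lay within 50 bp of 4.41% of IDR summits against 0.442% of windows centred 500 bp away, a ratio of 9.97 (exact adjusted p = 4.92e-85), and of 3.99% ± 0.250 of summits in the replicate top lists (SD, n = 3). The core promoter pattern called Motif 1 (GGTCACACT) lay at 2.41% against 0.167% (ratio 14.4, exact adjusted p = 2.25e-54, replicates 2.21% ± 0.0966). In the strongest 500 IDR peaks, DRE lay at 1.6% of summits against 0.4% of flanks and Motif 1 at 0.2% against 0.1%. At ranks 1725 to 3448, DRE lay at 5.57% of summits and Motif 1 at 3.25%. By quartile, DRE lay at 3.07% of the strongest IDR summits and 3.83% of the weakest (Fisher's exact p = 0.263). A pattern of the CTCF insulator type (AGGTGGCGC) lay at 0.406%, or 28 peaks, against 0.0435% (ratio 9.33, exact adjusted p = 4.59e-08, replicate ratio 6.07 ± 1.68). Its ratio was 18 without replicate 1, between Motif 1 (19.5) and DRE (11.7), and 11.5 without replicate 2, between Motif 1 (16.9) and DRE (11.3). Without replicate 3 it was 21, above Motif 1 (18.2) and DRE (13.5). The CTCF-type pattern matched 18, 23 and 21 summits in the sets without replicates 1, 2 and 3. Its ratios there rest on very few flank matches, so its order against Motif 1 and DRE is uncertain. The CTCF-type ratio was 18.7 against shuffled windows and 4.15 in windows of 100 bp on either side. It was 3.11 with flanks centred 1000 bp away, where that of DRE was 16.4. The A/T-rich patterns chosen because Bab proteins bind A/T-rich DNA were moderately more frequent, with TATATA at 7.93% against 6.02% (ratio 1.32, exact adjusted p = 9.55e-07, replicate ratio 1.28 ± 0.102), TAATAA at 14.8% against 10.4% (1.42, exact adjusted p = 9.29e-19, replicates 1.34 ± 0.195) and the homeodomain core TAATTA at 7.57% against 5.71% (1.32, exact adjusted p = 1.23e-06, replicates 1.23 ± 0.188).

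Runs of A (AAAAAAA, ratio 1.15, exact adjusted p = 0.00428) and the Pho pattern (GCCATTTT, ratio 1.54, exact adjusted p = 0.012) were also more frequent at summits. The CA repeat (ratio 0.697, exact adjusted p = 2.85e-06) and the Zelda pattern CAGGTA (0.777, exact adjusted p = 0.022) were less frequent. GAGA repeats (1.00), the E-box (0.989), and the GATA (0.976), AP-1 (1.11), Hox-Exd (1.29) and T-box (1.57) patterns did not pass the threshold, with exact adjusted p from 0.169 to 1. Each test was an exact permutation of the 3 windows within each peak, two-sided, with Benjamini-Hochberg adjustment over 16 patterns, and called 8 patterns higher and 2 lower.

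Summit windows held 38.8% G and C against 43.4% in the flanks. Against windows shuffled with their dinucleotide counts kept, TAATAA (ratio 0.906), TAATTA (0.852) and runs of A (0.889) were less frequent than chance and the CA repeat more frequent (2.34), while TATATA stayed more frequent (1.35, exact adjusted p = 5.1e-09), as did DRE (35.8) and Motif 1 (166.0). Motif 1 had very few matches in the shuffled windows, so the size of its ratio is uncertain. The Pho call was lost without replicate 2 (1.38, exact adjusted p = 0.181) and without replicate 3 (1.44, exact adjusted p = 0.0921), and the Zelda call without replicate 2 (0.763, exact adjusted p = 0.0528). The Hox-Exd pattern passed the threshold in each of the overlapping sets that left out a replicate (ratios 1.66 to 1.86), and the GATA pattern, as less frequent, without replicate 1 (0.672) and without replicate 2 (0.622).

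**Figure D4:**
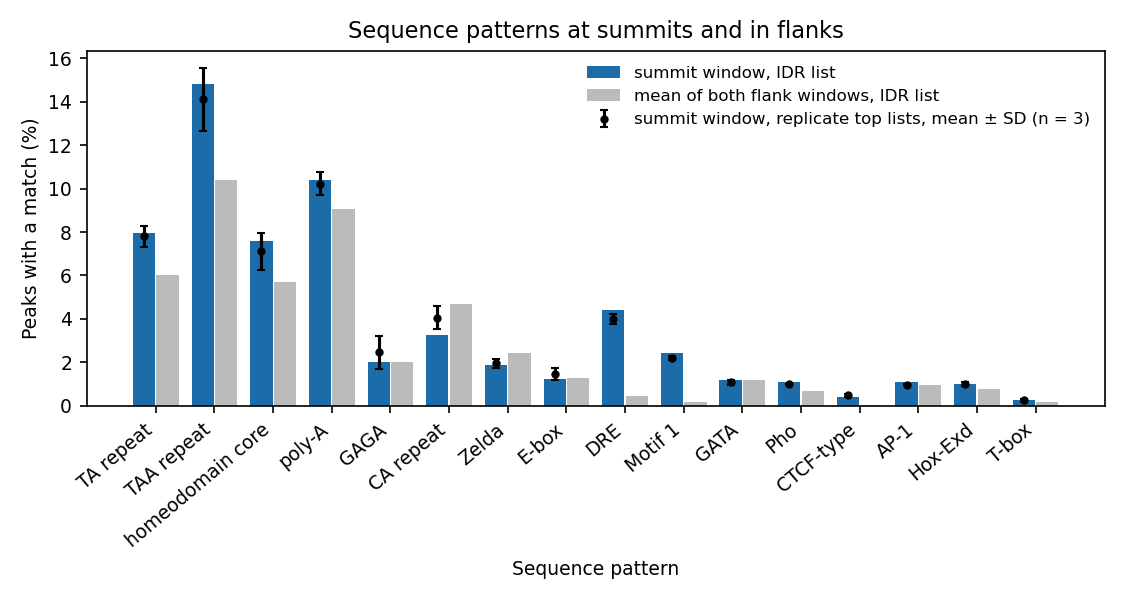
Share of peaks with a match to each of 16 sequence patterns (percent of peaks) in the summit window and in the flank windows of the IDR list, with the replicate top lists as mean ± SD (n = 3). DRE lay at 4.41% of summits against 0.442% of flanks.

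A scan of all 2080 sequences of 6 bases found 478 more frequent at the summits and 749 less frequent. Over all 6896 IDR peaks the largest ratios belonged to CGATAG (9.28% of summits against 2.51% of flanks, ratio 3.70), TATCGA (12.8% against 3.70%, ratio 3.45) and ATCGAT (10.3% against 3.42%, ratio 3.02), which are parts of or overlap the DRE. GTCACA (ratio 2.28), which lies within Motif 1, and ACACTG (ratio 2.27) followed. In the replicate top lists the ratio for CGATAG was 3.61 ± 0.212 and that for GTCACA 2.20 ± 0.101 (SD, n = 3). The test was the same exact permutation within peaks, with Benjamini-Hochberg adjustment over the 2080 sequences (adjusted p from 5.24e-118 to 9.37e-33 for these 5).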

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

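The test in this part was chosen after the data were seen. The pooled list, which the comparisons above used only through its IDR part, held 9 peaks at bab2, all ranked below the IDR list. These peaks lie in data that the comparisons leave out, but their number was within chance: genes matched to bab2 on length held 10.9 peaks of the pooled list on average (permutation p = 0.881, two-sided, 10000 random draws of genes), and the 17 at bab1 were within chance too (permutation p = 0.536). The strongest lay at the promoter of bab2 (chromosome 3L, 1177040 to 1177463, signal 199.1, rank 7036 of 30000), against a lowest signal of 201.9 in the IDR list. The top list of replicate 1 also held 1 peak at bab2 and those of replicates 2 and 3 held none. No explanation was tested.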

How the results depend on the processing

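The biotype-matched lists and the set of IDR peaks found in all 3 replicate top lists were chosen after seeing the data. Replicate agreement (54.2% to 70.6%), the promoter share (66.0% to 75.2%), the X ratio (1.27 to 1.36), the link of strength to promoters (rho 0.032 to 0.131), and the calls of ribosomal protein, proteasome, chemosensory, neuronal, DRE, Motif 1, CTCF-type and TATATA results kept their direction and their side of the threshold under every alternative run. The share of IDR peaks in all 3 top lists, which has no chance level because the lists share data, ran from 36.0% to 90.8%. The 6-mer scan gave 424 to 478 sequences higher at summits. At bab1 the count was 1 to 5, never beyond chance. Taking the top of the pooled list gave the IDR list itself and so no further value, and biotype matching could not be applied to tRNA genes, whose matched genes are nearly all tRNA genes. Where a call changed below, the cause was not tested, except that sets without a replicate and the strongest 3448 peaks hold fewer peaks by construction. Sets without a replicate also share the peaks found in all 3 top lists, so calls gained or lost in each are not independent.

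Among the strongest 3448 peaks, calls were lost for photoreceptor (ratio 0.595), cell cycle (1.66) and tRNA (1.37) genes and for Pho (1.29), and gained for pigmentation (0.143), Polycomb, trithorax and insulator (1.83) and heat shock (1.90) genes and for Hox-Exd (1.91). The Hedgehog and Dpp ratio turned below 1 in that set (0.418) without passing the threshold (adjusted permutation p = 0.0706). With each replicate left out, ratios ran from 1.35 to 1.76 for cell cycle genes (lost without replicates 1 and 3), 0.467 to 0.491 for photoreceptor genes (lost each time), 1.55 to 1.57 for Polycomb, trithorax and insulator genes (gained each time), 0.683 to 0.763 for Zelda (lost without replicate 2), 1.38 to 1.52 for Pho (lost without replicates 2 and 3), 1.66 to 1.86 for Hox-Exd (gained each time) and 0.622 to 0.730 for GATA (gained without replicates 1 and 2). In the peaks found in all 3 replicate top lists, photoreceptor (0.536), cell cycle (1.39) and Pho (1.48) calls were lost, and Polycomb, trithorax and insulator (1.72), GATA (0.600) and Hox-Exd (1.88) calls were gained. Of 210 counts of peaks at named genes under these peak sets, 22 fell to 0.

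With genes assigned by the nearest TSS, appendage (0.604) and photoreceptor (0.468) calls were lost, and Hox (0) and ecdysone (1.57) calls gained. With any TSS within 5 kb, 7 lists had more peaks than matched genes; photoreceptor (0.680) was lost, and germline (1.38), Polycomb, trithorax and insulator (1.37), innate immunity (1.42) and Hox (0) were gained.

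The chance model moved the gene lists most. Against circular shifts, which do not compare genes with genes, 17 lists had more peaks and 2 fewer. Appendage (0.857), muscle (0.586), photoreceptor (0.841) and neuroblast (0.503) calls were lost. Gained were germline (2.61), eggshell (3.28), Polycomb, trithorax and insulator (2.88), ecdysone (1.52), insulin (2.72), Notch (2.16), Wnt (1.69), Hedgehog and Dpp (2.00), EGFR and JAK/STAT (1.96), Hippo (2.11), innate immunity (2.73), heat shock (3.42) and metabolism (3.02). Without length matching, 14 lists had more peaks. Appendage (0.848), muscle (0.507) and photoreceptor (0.635) calls were lost, tRNA genes turned to fewer peaks (0.817), and germline (1.91), BTB (1.72), Polycomb, trithorax and insulator (1.94), ecdysone (1.98), insulin (1.78), Wnt (1.73), Hedgehog and Dpp (1.67), EGFR and JAK/STAT (1.84), Hippo (1.77), heat shock (1.65) and metabolism (1.81) were gained.

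Windows of 100 bp on either side gained GAGA (1.38) and T-box (1.68). Flanks 1000 bp away lost the CA repeat (0.926) and left 1 pattern less frequent. Against dinucleotide-shuffled windows 5 patterns were less frequent: TAATAA (0.906), TAATTA (0.852) and runs of A (0.889) turned, the E-box (0.751) was gained and Zelda kept its side, while the CA repeat turned to more frequent (2.34) and GAGA was gained (2.77). Depth is unknown from peak lists, so no limit from sequencing depth can be set on peaks that are missing.

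No paired analysis was possible because the labels give a single group.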

Other observations

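All lists and tests in this part were chosen after the data were seen, except for 4 tests written down before their result: those of crowded start sites, of background growing with transcription, of base composition and of start sites on X. Genes of mitochondrial protein synthesis and respiration carried many peaks. These are among 7 lists chosen by gene name. Of 73 genes of mitochondrial ribosomal proteins, 59 had an IDR peak against 19.3 for length-matched genes (ratio 3.06), led by mRpL41 (signal 5312), mRpS10 (4493), mRpS23 (3549), mRpL23 (1967) and mRpL24 (1804). The respiratory chain had 54 of 87 (ratio 1.93, ND-39 at 1048 and ND-24 at 834.3). Aminoacyl-tRNA synthetases, a list that mixes cytosolic and mitochondrial enzymes, had 27 of 32 (ratio 1.71, SerRS at 1119 and LeuRS-m at 924.8). Genes of cuticle proteins had 2 of 70 (ratio 0.0878; Cpr73D and Cpr51A), cytochrome P450 enzymes 13 of 75 (0.375; Cyp6u1 at 1416), and male seminal fluid proteins 2 of 47 (0.252; Sfp26Ad and Sfp24F), and larval cuticle proteins with chitin-binding obstructor proteins 0 of 51, where 13.8 were expected. Against 10000 random lists the adjusted permutation p was 0.0138 for seminal fluid proteins and 0.000233 for each of the other 6 lists, which rests on the smallest p the lists can give. In the replicate top lists 75.3% ± 1.37 of the mitochondrial ribosomal protein genes and 2.86% ± 1.43 of the cuticle protein genes carried a peak (SD, n = 3).

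The genes with the most IDR peaks were Mnt, a relative of the Myc and Max regulators, and the kinase gene Tlk with 18 each. They were followed by lncRNA:CR44357 (16), CG1677 (15), shn, Raf and CG33223 (13 each), and sbb, Svil and Eip75B (12 each), and neighbouring genes can share a peak. In the strongest 1000 IDR peaks the sequences of 6 bases with the largest ratios were TTTAAA (25.4% of summits against 7.25% of flanks, ratio 3.50), ATTTAA (ratio 3.19) and TACTAA (3.00), and none of the 10 largest was a part of DRE or Motif 1. Promoter elements differed by location. DRE lay at 5.90% of the 5014 promoter summits against 0.459% of their flanks, and at 0.425% of the 1882 other summits against 0.399%. The Zelda pattern was less frequent than in flanks at promoter summits (ratio 0.681, exact adjusted p = 0.00183) but not at the other summits (1.22, exact adjusted p = 0.790). The CTCF-type pattern was more frequent than in flanks at both locations (18 promoter peaks, 0.359% against 0.0499%, and 10 other peaks, 0.531% against 0.0266%). Its flank shares rest on very few matches.

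The first pattern is the coverage of ribosomal protein genes. With random lists matched on length and on the number of start sites of other genes nearby, 82 genes still stood against 36.7 expected (ratio 2.24, central 95% range 28 to 45 genes), which argues against crowded start sites as the whole cause. Promoter peaks at these genes were stronger than other promoter peaks, with a median signal of 489.8 over 107 peaks against 324.2 (random sets of other promoter peaks 296.7 to 360.5, permutation p = 0.0002, the smallest the sets can give). Immunoprecipitation background that grows with transcription could therefore account for them, since these genes are known to be highly transcribed, but binding by Bab1 would give the same value, and no library of untagged flies was used here. No biological explanation was tested.

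The second pattern is that A/T patterns (TATATA, TAATAA or TAATTA) marked the strongest peaks. They lay at 37.4% of the strongest quartile of IDR summits and 20.6% of the weakest (Fisher's exact p = 1.6e-27), and at 34.0% ± 4.06 and 20.9% ± 1.45 in the replicate top lists (SD, n = 3). In the strongest 500 peaks of the pooled list the share was 44.0% against 18.4% in their flanks, and it was 19.8% against 23.9% in its weaker 15000 peaks. Outside promoters the strongest quartile still had a ratio of 1.75 to its flanks (38.9% against 22.2%, 457 peaks), so its excess over flanks was not confined to annotated promoters. Over all 1882 IDR peaks outside promoters, TAATAA was more frequent than in flanks (ratio 1.27, exact adjusted p = 0.00469). There TATATA (1.29, exact adjusted p = 0.0507) and TAATTA (1.19, exact adjusted p = 0.278) did not pass the threshold. Weaker peaks outside promoters were not compared on their own. The test of the strongest quartile therefore does not decide whether position at core promoters gives the contrast between strong and weak peaks. Base composition cannot be told apart from sequence preference, because shuffled windows with the same dinucleotides matched nearly as often (ratio 1.07, exact permutation p = 0.0624) and the shuffle keeps the TA steps that a preference for A/T-rich DNA could itself require. No biological explanation was tested.

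The third pattern is the density on X. Annotated start sites were not denser there (167.6 per Mb against 179.9 on the autosome arms), and summits per start site were 1.39 times as frequent on X (0.383 against 0.276, permutation p = 1e-05, the smallest the permutations can give), which argues against the density of start sites. Leaving out the outermost and innermost 1 Mb of each arm gave a ratio of 1.33. A candidate explanation that stays open is a control library with fewer copies of X than these females carry, which was not tested because the control was not used here. No biological explanation was tested.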
